A study of Mus musculus with 8 samples.

How the data were processed

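Gene expression was measured with an Affymetrix mouse gene array in epididymal white adipose tissue (eWAT) of 8 male mice, 3 wild type (WT) and 5 Abhd15 knockout (KO), with 1 array per mouse and 200 ng of RNA per array. Genotype and replicate number were taken from the sample titles. The deposited table holds 1 log2 value per probe set and array, made with RMA (robust multi-array average: background correction, normalization across arrays and probe summary), and RMA and the package oligo are named in the submitters' processing notes. The series design text names Expression Console, so which of these tools made the deposited values is not settled. Tool versions, any centring or filter, the array annotation used and a genome build are not given in the sources used here. The values were used as deposited, without renormalization. The distributions were close across arrays, with medians over all probe sets between 2.93 and 3.12. RMA compresses differences of dim probe sets, so a small fold change at a low value is less certain than at a high one. Array data carry no counts, and the number of arrays limits the precision.

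Probe sets were named from a table that pairs them with the platform annotation, which can be old. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none listed. Of the single-symbol probe sets, 23328 were matched by Entrez identifier to a mouse gene table of assembly GRCm38.p6, used for current symbols, for the chromosome and for which genes lie next to each other. Its positions are not given, since no build is named for the array. Of several probe sets of a gene (1082 genes), the one with the highest mean over all 8 arrays was kept, leaving 22180 genes. Genes with a mean at or above the median of these means (3.61) were tested, 11090 in all.

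KO was compared with WT in limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with the Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every p-value of a gene below is limma's unless another test is named. Single values were also compared by an exact two-sided permutation test over the 56 ways of dividing 8 arrays into 3 and 5, whose smallest possible p is 0.0357. Of 30 fixed gene lists, the 25 with at least 3 tested genes were compared with all other tested genes by camera (preset correlation between genes of 0.01), adjusted over the 25 lists. Alternatives were camera with the correlation estimated from the data and fry, which tests whether the genes of a list move on balance in one direction. Within a list, p-values were also adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

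The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule, Abhd15 and Pde3b are always named. Per direction, up to 12 genes past the threshold with no overlap between the groups are named by size. Since none passed, the places were filled with the genes of smallest unadjusted p among those with an absolute log2 fold change of at least 0.5. Of each list described, up to 4 tested members with the smallest unadjusted p are named. Predicted genes, microRNAs and small nucleolar RNAs are not named, and substrain markers and neighbours of Abhd15 are named where the unadjusted p was under 0.05. Which 13 of the 30 lists have their members named was decided after the values had been seen. The fits without WT 1 and KO 4, without KO 1 and KO 2, without KO 1 to KO 3, and with the second Abhd15 probe set were also chosen after seeing the data. Genes and probe sets named outside the rule are said to be so where they appear.

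WT and KO share the replicate numbers 1 to 3, and the sources used here do not say what a number stands for. The numbers were checked by correlating, over the tested genes, the deviations of same-numbered arrays from their group means. The correlation was 0.133 for number 1, 0.103 for number 2 and 0.192 for number 3. All exceed 0.1, so by a rule fixed beforehand the numbers count as pairing in the fit with the replicate block and in the comparison of splits. The main limma fit, as planned, and the exact permutation tests over 56 splits leave the number out. The evidence is thin: WT 2 deviated as much with KO 1 (0.105) as with KO 2, and with the KO mean taken over replicates 1 to 3 alone the correlations were 0.196, 0.0499 and 0.219. The fit with the replicate number as a block is an alternative, in which KO 4 and KO 5 add nothing to the contrast. No 2 arrays were identical.

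The procedure was tested on simulated data made from the real means and spreads of the 11090 genes, with independent noise, in 10 runs with 200 changed genes each. For KO against WT it called 13.6% of changes of 0.5 on the log2 scale, 64.4% of changes of 1 and 94.5% of changes of 2, and 5.63% of all calls were false. Lists shifted by 0.3 were called in 100% of cases and unshifted lists in 1.90%. Real genes of a list vary together, which independent noise leaves out.

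Other alternatives were no filter on dim genes, a filter at the 25th percentile, the mean of a gene's probe sets, a trended and robust prior, array weights, repeated quantile normalization, centring each array on its median, and leaving out each array in turn. The probe sets with no listed gene or with several were left out of the gene test and fitted together with all others in a separate fit.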

Results

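Transcript levels in eWAT, the visceral fat pad attached to the epididymis, were compared between Abhd15 KO mice (n = 5) and WT mice (n = 3) on a C57BL/6J background. The mice were 14 weeks old, had no food overnight and then ate chow for 1 h before the tissue was taken, so the samples represent the early refed state. ABHD15 is an adipocyte protein of the alpha/beta-hydrolase family that has been linked to phosphodiesterase 3B, the enzyme through which insulin lowers cyclic AMP and restrains lipolysis. The comparison asks how the loss of Abhd15 alters gene expression in fat after feeding. Each of the 8 arrays gave values for 41345 probe sets, and values of any pair of arrays correlated across probe sets at r = 0.962 to 0.978.

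The signal of Abhd15 itself was 6.32 ± 0.157 in WT (log2, SD, n = 3) and 5.89 ± 0.271 in KO (SD, n = 5) at its brighter probe set, a log2 fold change of -0.43 (SE 0.170). The difference did not pass the threshold (adjusted p = 0.423 in limma), and the exact two-sided permutation p was 0.0714. The array labelled KO 3, at 6.27, lay inside the WT range of 6.15 to 6.45, whereas the other 4 KO arrays lay below it. A second, dimmer probe set of Abhd15 read 4.24 ± 0.236 in WT (SD, n = 3) and 3.54 ± 0.399 in KO (SD, n = 5), a log2 fold change of -0.70, and there too the array labelled KO 3 (4.19) lay within the WT values. Its exact permutation p was 0.107. One more probe set, annotated to Abhd15 and Trp53i13 together and so not assignable to either, read 4.70 ± 0.106 in WT (SD, n = 3) and 4.90 ± 0.238 in KO (SD, n = 5), a log2 fold change of 0.20 (exact permutation p = 0.25). Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so they do not check the genotype labels.

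**Figure D1:**
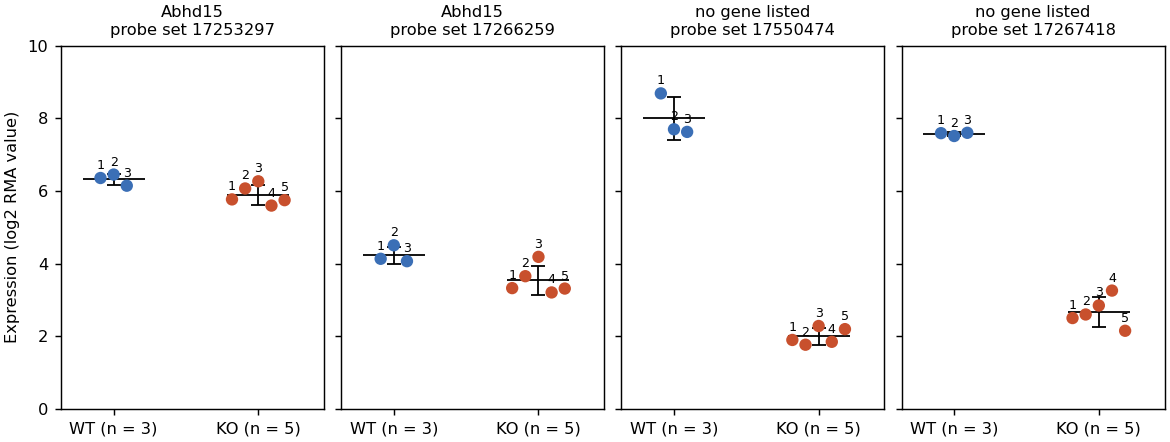
Expression (log2 RMA value) at both probe sets annotated to Abhd15 alone and at both probe sets without a listed gene that differed most, one point per array with its replicate number, with the group mean and SD as bars. KO 3 sits at the WT level for Abhd15 (6.27 and 4.19), while at the 2 unnamed probe sets all 5 KO arrays lie far below all 3 WT arrays.

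No gene passed the threshold after adjustment over the 11090 genes tested with limma. At an unadjusted p under 0.05, 1164 genes differed (448 higher and 716 lower in KO), against 554.5 expected by chance, and 946 genes (8.53%) had no overlap between the groups, where chance gives 3.57%. The split between higher and lower depended on the scaling and on KO 5. With the values as deposited 38.5% of the 1164 were higher, and when each array was centred on its median 48.7% of 1168 were. Without KO 5, 48.1% of 1596 were higher. Over the tested genes KO 5 had a median of 5.929, against 6.035 to 6.0675 in the other arrays, and the lowest array weight (0.335). The count of 1164 fell to 745 without WT 1. With the replicate number as a block, which rests on KO 1 to KO 3, 2 genes passed (Fosb and Ranbp3l, both higher, the latter named after its value was seen) and 1997 had an unadjusted p under 0.05.

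The genes named in this paragraph and the next did not pass the adjusted threshold in the main fit. Apart from Pde3b, they were picked for the smallest unadjusted p and not for size. For each of them all KO arrays lay beyond all WT arrays, which such a choice favours, whereas Abhd15 overlapped. Among those higher in KO, Npr3, the clearance receptor for natriuretic peptides, went from 9.27 ± 0.560 in WT (SD, n = 3) to 10.8 ± 0.275 in KO (SD, n = 5), a log2 fold change of 1.51 (SE 0.245). The angiogenic ligand Angpt1 had a log2 fold change of 1.48, the endocytic recycling gene Ehd3 1.27, the nuclear receptor Nr1d1 of the circadian clock 0.98, the stress-response gene Ndrg1 0.92, and BC051226 0.91. The kinase Sik1, which responds to cyclic AMP, was at 0.89, the membrane protease Mme at 0.86, the matrix glycoprotein Thbs1 at 0.82, the ERK phosphatase Dusp5 at 0.81, the glycogen-binding protein Stbd1 at 0.78 and the lysosomal transporter Slc46a3 at 0.66.

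Among the tested genes, the most negative log2 fold change was that of Angptl8, an insulin- and feeding-induced inhibitor of lipoprotein lipase activity. It read 8.26 ± 0.539 in WT (SD, n = 3) and 5.69 ± 0.847 in KO (SD, n = 5), a log2 fold change of -2.57 (SE 0.441, adjusted p = 0.134). Gpam and Gpat3, which catalyse the first acylation step of glycerolipid synthesis, had log2 fold changes of -1.14 (SE 0.202) and -0.69 (SE 0.120), the latter shrinking to -0.31 (adjusted p = 0.462) with the mean of its probe sets. Pik3cb, a catalytic subunit of phosphoinositide 3-kinase, was at -1.03. Pde3b read 11.4 ± 0.222 in WT (SD, n = 3) and 10.8 ± 0.394 in KO (SD, n = 5), a log2 fold change of -0.67 (SE 0.222, adjusted p = 0.352). The others were the secreted pheromone carrier Mup20 (-1.51), Erdr1 (-1.49), the proteoglycan Prg4 (-1.30), the signalling adaptor Bcar3 (-0.98), the endothelial surface protein Ecscr (-0.92), the growth factor Fgf7 (-0.92), Syt12 (-0.76) and the chromatin remodeller Chd7 (-0.64). The smallest adjusted p, 0.0752, was shared by Prg4, BC051226, Bcar3, Erdr1 and Mup20. With array weights, 40 genes passed (16 higher, 24 lower), and with a trended, robust prior Prg4, Bcar3 and Erdr1 passed. Without KO 5, 5 genes passed.

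**Figure D2:**
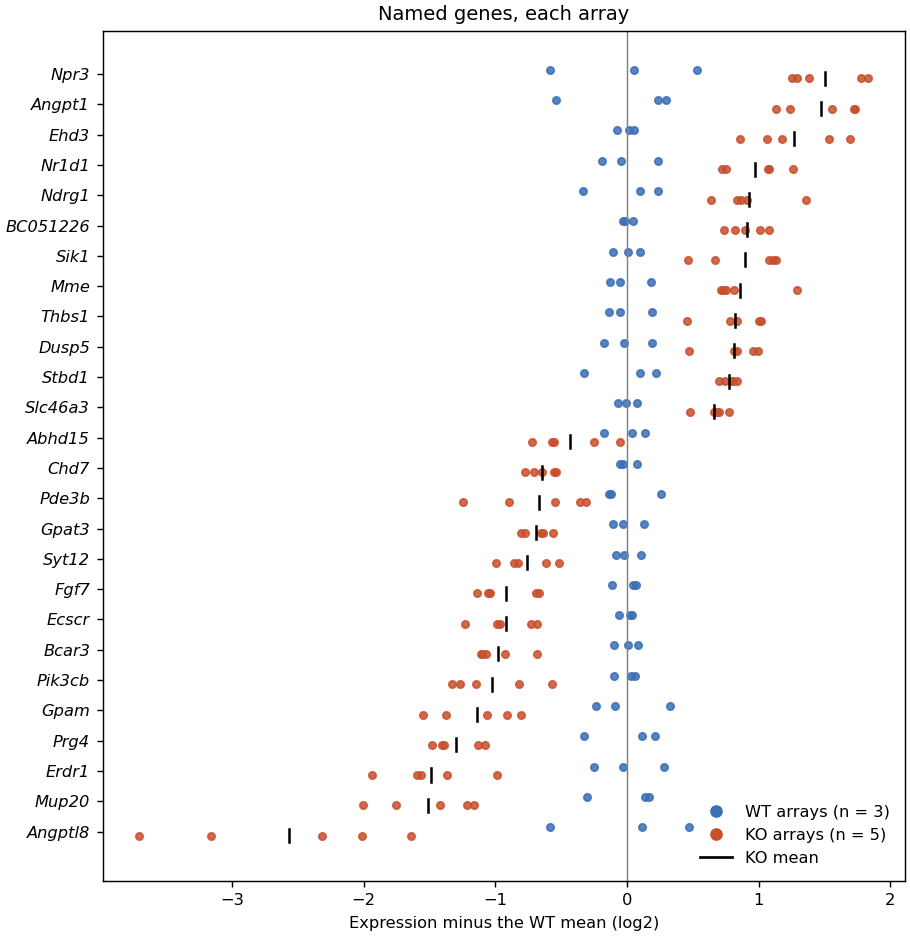
Expression of each named gene minus its WT mean (log2), with WT arrays in blue, KO arrays in red and the KO mean as a bar. For all genes but Abhd15 the 5 KO arrays lie on one side of the 3 WT arrays, which a choice by smallest unadjusted p favours. The changes run from Angptl8 at -2.57 to Npr3 at 1.51.

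Among the lists of adipocyte metabolism, none passed as a list at the main settings and single members stood out. In the list of triglyceride storage and fatty acid uptake, 5 of 17 tested genes were higher and 12 lower in KO (camera adjusted p = 0.676). Adjusted over the list alone, Gpam fell and Angptl4, a lipoprotein lipase inhibitor induced by fasting, rose (log2 fold change 0.98), while the acyltransferases Dgat1 (-0.66) and Agpat2 (-0.45) did not pass. Of 16 de novo lipogenesis genes 10 were higher and 6 lower (adjusted p = 0.341), and none passed, the nearest being Slc25a1 (0.36), Mlxipl (-0.41), Elovl6 (0.60) and Pnpla3 (0.53). Of 15 genes of lipolysis and its cyclic AMP control, 6 were higher and 9 lower (adjusted p = 0.855). Their mean (-0.005) and median (-0.11) were below 0 while camera gave the list an upward direction. After Pde3b the members nearest to the threshold were Npr1 (-0.30), Prkaca (0.35) and Mgll (0.35, but 0.12 without WT 1).

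Of 19 genes of insulin signalling and glucose uptake, 4 were higher and 15 lower (adjusted p = 0.173). The list passed without the level filter (adjusted p = 0.0353) but, with the filter, not at an estimated correlation (0.784). Its mean was lower in all 5 KO arrays than in any WT array (group means 7.52 and 7.63, exact permutation p = 0.0357, the smallest possible and not adjusted). The highest KO array (KO 3, 7.619) lay barely below the lowest WT array (WT 1, 7.63). Chance gives such a separation for 3.57% of values, and the means of 30 lists were compared. The insulin receptor Insr fell when adjusted over the list alone (-0.54, SE 0.115), while Grb10 (-0.58), Grb14 (0.97) and Irs2 (0.41) did not pass. In the mature adipocyte list 6 of 16 genes were higher and 10 lower (adjusted p = 0.704). The lipid droplet gene Plin4 fell by 0.51 on the log2 scale, adjusted over the list alone, whereas Pparg (-0.47), Cebpa (0.32) and Acvr1c (-0.44) did not pass. Of 16 fatty acid oxidation genes 9 were higher and 7 lower (adjusted p = 0.162), and the list passed without WT 1 (adjusted p = 0.00857), but not with an estimated correlation (0.784), and its mean overlapped between the groups (exact permutation p = 0.536). Ppargc1b fell, adjusted over the list alone (-0.72), and Pdk4 (0.67), Acadm (0.32) and Etfdh (0.29) did not pass. Of 7 thermogenic genes 6 were higher and 1 lower (adjusted p = 0.148), with Cidea at 0.95, Cox8b at 0.54, Ppargc1a at 0.30 and Prdm16 at -0.31, none of them passing. That list passed with the mean of a gene's probe sets (adjusted p = 0.0436) and without WT 3 (0.0327), but not with an estimated correlation (0.784) or fry (0.324). Its mean was higher in all 5 KO arrays than in any WT array (group means 5.26 and 4.95, exact permutation p = 0.0357, the smallest possible and again not adjusted). The lowest KO array (KO 5, 5.148) lay barely above the highest WT array (WT 3, 5.144). In the cholesterol synthesis list 7 of 13 genes were higher and 6 lower (adjusted p = 0.665), and its mean was slightly below 0 (-0.014) while its median and camera's direction were above. Adjusted over the list alone, Hmgcs1 fell (-1.01) and Mvk rose (0.60), while Nsdhl (0.38) and Fdft1 (0.58) did not pass. The extracellular matrix list had 10 genes higher and 10 lower (adjusted p = 0.704), its median being above 0 and its mean below, and Postn (-0.55), Lox (-0.49), Col5a2 (-0.27) and Col4a1 (-0.31) did not pass.

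Of the 25 lists tested, 3 passed with camera's preset correlation, and none did with an estimated correlation or with fry. The immediate early and heat shock list, made of genes induced within minutes by stimulation, handling or stress, was higher in KO (13 of 15 genes, adjusted p = 0.00140, and adjusted p = 0.784 with an estimated correlation). No member passed, adjusted over all genes or over the list alone. The nearest were Fosb (fitted 2.20, with a WT mean of 2.97 near background), Fos (1.60), Nr4a1 (1.38) and Egr2 (1.22). The WT means of Fos (3.53) and Egr2 (3.28) also lay below the level filter (3.61). Fosb, Fos and Egr2 were thus tested only because of their KO values, and their fitted changes are less certain. The heat shock genes, named after their values were seen, went both ways: Hspa1a (0.71) and Hspa1b (0.19) were higher, Hsph1 (-0.23) and Dnajb1 (-0.003) lower. The list mean was 7.18 in KO 1, 7.17 in KO 2 and 6.33 in KO 3, above the highest WT array (5.97), but 5.82 in KO 4 and 5.90 in KO 5, inside the WT range (exact permutation p = 0.143). The mean of the 2 erythroid genes measured, too few for a list test, was also high in KO 1 (5.30) and KO 2 (5.50), against 4.12 to 4.13 in WT and 3.89 to 4.16 in the other KO arrays. Without KO 1 and KO 2 the immediate early and heat shock list did not pass (adjusted p = 0.171). The mean log2 fold change of its genes was then 0.25 (SE over genes 0.119) against 0.71 (SE 0.199) with all arrays. With KO 3 left out as well, the mean was 0.087 (SE 0.0626), with 7 genes higher and 8 lower.

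The endothelial list was lower in KO (11 of 15 genes, adjusted p = 0.00625, and adjusted p = 0.784 with an estimated correlation). The list mean was below the lowest WT array in 4 of 5 KO arrays, and in KO 5 it lay inside the WT range of 7.15 to 7.43 (exact permutation p = 0.0714). Kdr, the main receptor for vascular endothelial growth factor, fell when adjusted over the list alone (-0.69, SE 0.131), and Pecam1 (-0.64), Egfl7 (-0.48) and Eng (-0.48) did not pass. Cldn5, named after its value was seen, went the other way (0.61). The mean log2 fold change of the genes was -0.26 (SE over genes 0.0941). The call was lost without WT 2 (adjusted p = 0.165, mean -0.20), and narrowly without KO 1 and KO 2 (adjusted p = 0.0512, mean -0.25). It was also lost without KO 1, KO 2 and KO 3 (adjusted p = 0.141, mean -0.19). The endoplasmic reticulum stress list was lower in KO (14 of 16 genes, adjusted p = 0.0244, and adjusted p = 0.784 with an estimated correlation). Its mean was below the lowest WT array in 4 of 5 KO arrays, and in KO 4 (8.14) it lay inside the WT range (exact permutation p = 0.107). The members nearest to the threshold were Dnajb9 (-0.59), Atf6 (-0.36), Chac1 (-0.76) and Ddit3 (-0.47), and none passed. The mean log2 fold change of its genes was -0.24 (SE over genes 0.0574). That call was lost with the replicate block (adjusted p = 0.0621, mean -0.21), with array weights (0.0705, -0.19), without WT 1 (0.0521, -0.20) and without KO 5 (0.230, -0.16). With a mean no smaller, it was also lost without KO 1 and KO 2 (0.0866, -0.25, SE 0.0527) and without KO 1, KO 2 and KO 3 (0.0920, -0.28).

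**Figure D3:**
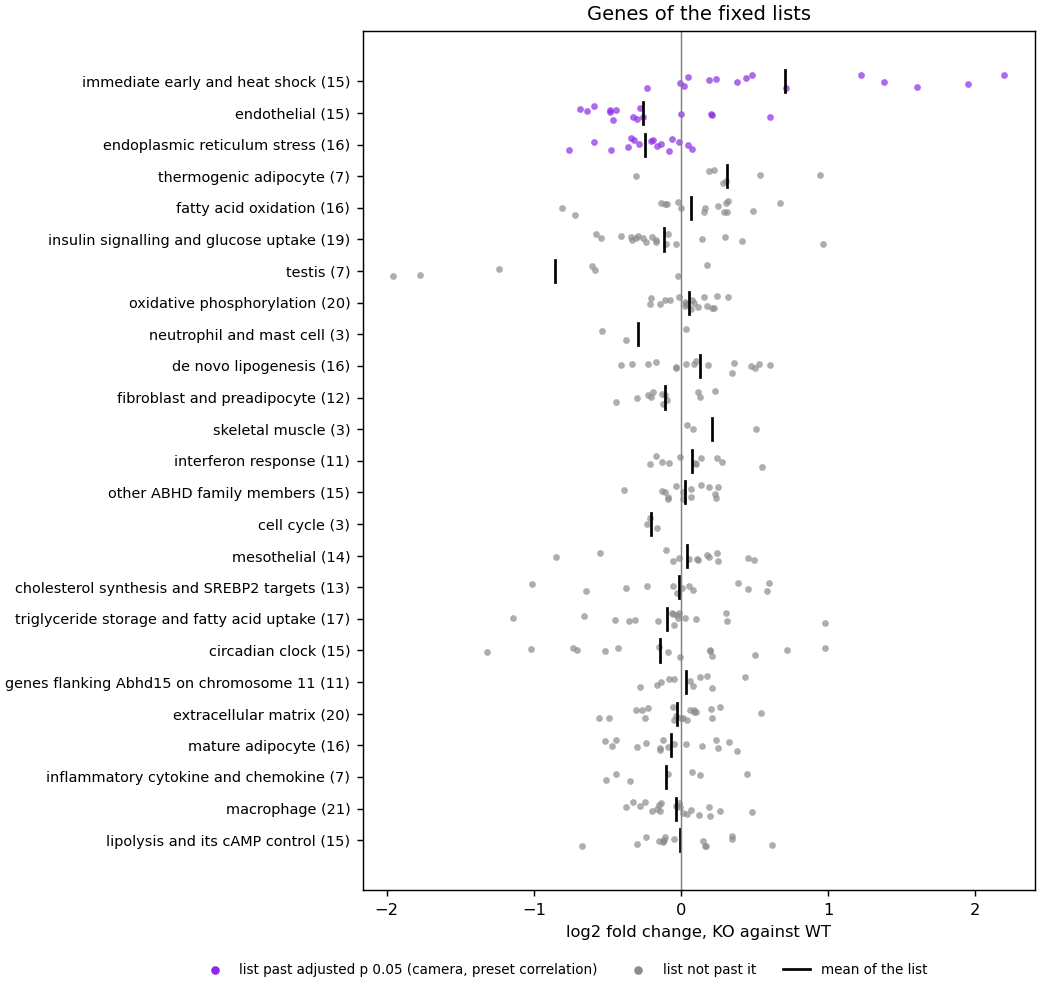
Log2 fold change (KO against WT) of each tested gene of the 25 lists, one point per gene, with the list mean as a bar and the number of genes in brackets. Purple lists passed with camera's preset correlation (immediate early and heat shock above 0, endothelial and endoplasmic reticulum stress below 0), and no list passed with an estimated correlation.

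In the circadian clock list 6 of 15 genes were higher and 9 lower, and the list as a whole did not pass (adjusted p = 0.677). Adjusted over the list alone, 4 members passed: Nr1d1 rose, and the transcriptional repressors Bhlhe40 (-1.32, SE 0.275), Nfil3 (-1.02, SE 0.230) and Bhlhe41 (-0.73, SE 0.239) fell. Adjusted over the 328 genes of all tested lists together, only Nr1d1, Gpam (both adjusted p = 0.0352) and Kdr (0.0399) passed. The other genes said to fall or rise when adjusted over their list alone did not.

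Lists for other cell types and processes did not pass either at the main settings. The fibroblast and preadipocyte list had 3 of 12 genes higher (adjusted p = 0.416), the macrophage list 8 of 21 (0.855), inflammatory cytokines and chemokines 3 of 7 (0.801), the interferon response 6 of 11 (0.561), skeletal muscle 3 of 3 (0.416) and the cell cycle 0 of 3 (0.587). In the neutrophil and mast cell list 1 of 3 genes was higher (0.224), and Kit (-0.54) fell when adjusted over the list alone. In the mesothelial list 9 of 14 were higher (0.587), and Muc16 (-0.85) fell when adjusted over the list alone. Kit and Muc16 were named after their values were seen. Oxidative phosphorylation had 14 of 20 genes higher (0.173) and passed with array weights (adjusted p = 0.0180), with the replicate block (0.0261), without WT 1 (0.0490) and without KO 5 (0.0417), but not with an estimated correlation (0.825), and its mean overlapped between the groups (exact permutation p = 0.714). Other ABHD family members had 9 of 15 higher (0.561). Of the genes flanking Abhd15 on chromosome 11, 6 of 11 were higher (0.704), with Slc6a4 at 0.44 (unadjusted p = 0.0190 in limma, adjusted p = 0.370). Too few genes were tested for the lists of T and NK cells (2 genes), B and plasma cells (1), erythroid cells (1) and C57BL/6J against C57BL/6N substrain markers (2), and no substrain marker reached an unadjusted p of 0.05.

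Transcripts of the male reproductive tract appeared in single arrays. Of the testis list, 1 of 7 tested genes was higher in KO (adjusted p = 0.173). The list passed as lower in KO without the level filter (adjusted p = 0.00165), with the filter at the 25th percentile (0.00302), without WT 3 (0.000700) and without KO 4 (0.0208), but not with an estimated correlation (0.784), and its mean overlapped between the groups (exact permutation p = 0.321). It was 6.31 in WT 1, 5.56 in WT 2 and 5.71 in KO 4 but 3.84 to 4.37 in the other arrays. No gene of the epididymis and seminal duct list reached the level filter. The mean of the 16 measured was 4.18 in KO 4 and 2.85 in WT 1 against 2.01 to 2.26 elsewhere. In WT 1 the rise lay in the seminal vesicle genes Svs2, Svs4 and Svs5, and no other member was highest in that array. Without WT 1 and KO 4 no gene passed and 732 had an unadjusted p under 0.05, while 5 lists passed, the 3 above with fatty acid oxidation and oxidative phosphorylation.

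**Figure D4:**
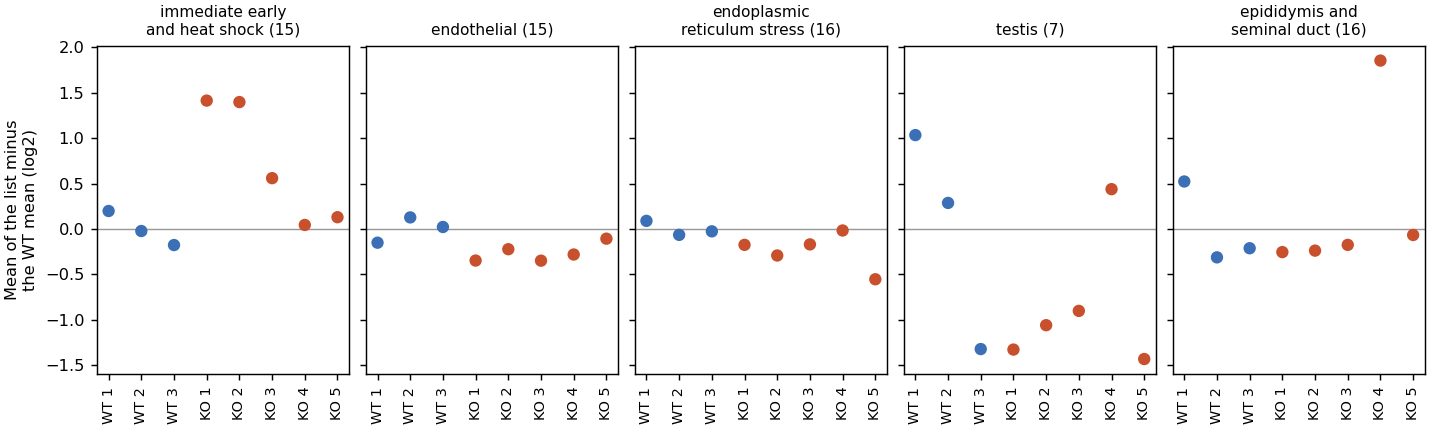
Mean of 5 gene lists in each array minus the WT mean (log2), with WT arrays in blue, KO arrays in red and the number of genes in brackets. The immediate early list stands high in KO 1, KO 2 and KO 3 only, and the testis list in WT 1, WT 2 and KO 4. The epididymis and seminal duct list stands high in KO 4. Its smaller value in WT 1 comes from the seminal vesicle genes Svs2, Svs4 and Svs5.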

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

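All tests in this part were chosen after the result had been seen. A window around Abhd15 set by distance had been chosen beforehand; it was replaced by one in gene order because the array's genome build is not named, and both are given.

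Among the probe sets left out of the gene comparison, 3 had an adjusted p under 0.05 in a limma fit over all 41345 probe sets, all lower in KO and all without a listed gene. Probe set 17550474 read 8.0 ± 0.592 in WT (SD, n = 3) and 2.00 ± 0.227 in KO (SD, n = 5), a fitted log2 fold change of -6.00 (adjusted p = 9.33e-05 in limma). Probe set 17267418 read 7.57 ± 0.0482 in WT (SD, n = 3) and 2.67 ± 0.412 in KO (SD, n = 5), a fitted log2 fold change of -4.90 (adjusted p = 0.000101 in limma). The fall was smaller at probe set 17208813, from 4.70 ± 0.197 in WT (SD, n = 3) to 3.09 ± 0.184 in KO (SD, n = 5). Its log2 fold change was -1.61 (adjusted p = 0.0323 in limma). Nlrp1c-ps, a pseudogene on chromosome 11 too dim for the gene comparison and picked after its values were seen, read 3.77 ± 0.609 in WT (SD, n = 3) and 1.67 ± 0.194 in KO (SD, n = 5), a fitted log2 fold change of -2.10 that did not pass (adjusted p = 0.126 in limma over all genes without the level filter). The KO means of Nlrp1c-ps and of probe sets 17550474 and 17267418 lie below the median of every array (2.93 to 3.12). Signal is not told from background there, so their fitted values do not measure the full size of the fall.

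The tables argue against 2 libraries with exchanged labels for this pattern, since an exchange of 1 WT and 1 KO label would make another split of the arrays the true one. Over all probe sets, the largest gap between the groups was 5.343 on the log2 scale with the labels as given. It was at most 2.708 in the 15 splits that exchange such a pair. The difference is larger than any range within a group at probe sets 17550474 and 17267418 (at most 1.106). A floor in KO can only narrow such a gap. KO 3, whose Abhd15 signal lay in the WT range, lay with the other KO arrays at probe sets 17550474 and 17267418. Both were picked because they differ between the groups as labelled, so this does not check the label of KO 3. A single wrong label without an exchange was not tested. A chromosome 11 interval carried over from another strain could also lower hybridisation at single probe sets. Among the 200 neighbouring genes on each side of Abhd15, 34 of 400 (8.5%, exact 95% interval 5.96 to 11.7%) had an unadjusted p under 0.05 in limma, against 8.42% of other genes, which is percentile 39.9 of windows of as many genes. The window by distance gave 9.35% and percentile 61.5. Neither excludes an interval that alters few probe sets, and 128 genes lie between Nlrp1c-ps and Abhd15, so this explanation and an effect of the genotype cannot be told apart.

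The mean of the 16 epididymis and seminal duct genes in KO 4 was 4.18, against 2.07 to 2.26 in the other KO arrays. The mean of the testis list was 5.71 there, against 3.84 to 4.37. Adam7 (10.2), Spint4 (10.3), Rnase9 (8.60) and Lcn5 (8.56) led the epididymis genes there. Cyp17a1 of the testis list, named after its values were seen, read 7.96 in KO 4 against 2.12 to 3.12 in the other KO arrays, and 4.83 in WT 2. WT 1 instead held seminal vesicle genes (Svs5 at 7.42, Svs4 at 6.45, Svs2 at 6.38) and the sperm genes Tnp1 (6.91) and Tnp2 (6.86), and WT 2 the sperm genes Tnp2 (5.53) and Tnp1 (4.88). The tables argue against the genotype as the only cause, since arrays of 1 genotype differed: the testis mean ranged over 2.36 within WT and the epididymis mean over 2.11 within KO, while the mean of no other list ranged over more than 1.60 within WT or KO. An effect of the genotype in some KO mice only was not tested. RNA of adjacent reproductive tract tissue taken up at dissection is a candidate explanation. Of the 16 epididymis and seminal duct genes, 6 were highest in KO 4, and 5 of these lay over 2 log2 units above every other array. By chance any of the 8 arrays leads as many genes with an exact one-sided p of 0.0796. This count leaves the explanation open, since it ignores the size of a lead and includes genes dim in every array. It also includes the seminal vesicle genes Svs2, Svs4 and Svs5, all highest in WT 1, so it is not a count of epididymis genes alone. Single leads were large: Spint4 read 10.3 in KO 4 against 1.652 to 2.407 in the other arrays, and Rnase9 8.60 against 1.515 to 1.845. Of the testis list, Odf1 read 10.5 to 10.9 in every array, so it does not mark single arrays.

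Other single arrays stood apart from the remaining KO arrays. Mme read 9.14 in KO 4 against 8.57 to 8.67. Fdft1 read 7.47 in KO 5 against 8.61 to 8.84. Ranbp3l read 2.85 in KO 5 against 4.88 to 5.42, and Podxl read 6.85 in KO 5 against 6.14 to 6.19; Podxl was named because it passed without that array, and Ranbp3l passed there too. The mean of the mesothelial list was 5.41 in KO 1 against 5.85 to 5.92. In all, 111 values were tested for such a gap and 7 had one, where chance gives about 1 in 20. Podxl and Ranbp3l, among the 7, passed with KO 5 left out, which favours a gap in KO 5. The count of 7 is therefore not a fair comparison with chance.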

How the results depend on the processing

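The fits named here that leave out more than 1 array and the second Abhd15 probe set were chosen after seeing the data. Abhd15 and the heat shock genes apart, 80 genes are named with a change in KO and passed the level filter. All of these kept their direction under every setting that tested them. Prdm16 fell below the filter with the mean of a gene's probe sets. Some changes shrank to under 50% of their log2 size: Gpat3 (-0.31, mean of probe sets), Acvr1c (-0.08, block), Mgll (0.12, without WT 1), Agpat2 (-0.22, without WT 1 and KO 4), 7 genes without KO 1 and KO 2, and 15 without KO 1, KO 2 and KO 3. Abhd15 stayed below 0 and short of the threshold throughout (-0.52 to -0.36 when single arrays were left out, -0.56 with the mean of its probe sets, -0.70 at its second probe set). No gene passed with another level filter, the mean of a gene's probe sets, repeated quantile normalization or median centring. By contrast, 3 genes passed with a trended and robust prior, 40 with array weights, and 0 to 5 when single arrays were left out. The 5 that passed without KO 5 were Ranbp3l, Bcar3, Angptl4, Podxl and Prg4, of which Ranbp3l and Podxl were named after their values were seen. Counts at an unadjusted p under 0.05 in limma were 1871 without the filter on dim genes (more genes tested), 1873 with array weights, and 745 (without WT 1) to 1596 (without KO 5) when single arrays were left out. Without WT 1 and KO 4 the count was 732. Without KO 1, KO 2 and KO 3 it was 1238, and 1 gene passed the adjusted threshold. Centring or repeated quantile normalization moved the share of higher genes at an unadjusted p under 0.05 from 38.5% to 48.7% and 48.2%. Leaving out KO 5 moved this share to 48.1%. The number of lists that passed was 6 without the filter (also insulin signalling, testis, and B and plasma cells), 2 to 5 when single arrays were left out (2 without WT 2, 5 without WT 3), 5 without WT 1 and KO 4, and 0 without KO 1 and KO 2, without KO 1, KO 2 and KO 3, with an estimated correlation and with fry. The adjusted p of the called lists ranged from 1.36e-05 to 0.0239 (immediate early and heat shock), 0.000133 to 0.165 (endothelial) and 0.00231 to 0.230 (endoplasmic reticulum stress) when single arrays were left out. In simulated data with independent noise, the self-test called most changes of 1 on the log2 scale and few of 0.5. Smaller changes would thus mostly be missed with 8 arrays. The rate for changes of 1 need not hold for the real data, in which genes vary together. No gene passed there at the main settings, not even Angptl8 (-2.57, adjusted p = 0.134 in limma) or Npr3 (1.51, adjusted p = 0.122 in limma). The lack of calls therefore does not show that changes of 1 or more are absent. Where not stated, the cause of a change was not tested.

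With the replicate block, 2 genes passed and 1997 had an unadjusted p under 0.05, Abhd15 was at -0.28, the endoplasmic reticulum stress list was lost (adjusted p = 0.0621) and oxidative phosphorylation gained (0.0261). No other list call changed. Lists that turned direction with the block, none of them passing, were triglyceride storage and fatty acid uptake (adjusted p = 0.627), mature adipocyte (0.542), macrophage (0.333), inflammatory cytokine and chemokine (0.539), extracellular matrix (0.635), cell cycle (0.907) and the genes flanking Abhd15 (0.755). The cause was not tested, though the block leaves KO 4 and KO 5 out of the contrast.

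The lists below did not pass where they turned direction; of them, oxidative phosphorylation passed in 5 other settings. The cause was not tested. Lipolysis turned without the filter (adjusted p = 0.790), at the 25th percentile (0.861), with fry (0.887), without KO 1 and KO 2 (0.294) and without KO 1, KO 2 and KO 3 (0.103). The inflammatory list turned without the filter (0.591), at the 25th percentile (0.543), with array weights (0.909) and without WT 1 and KO 4 (0.739). The genes flanking Abhd15 turned without the filter (0.950) and with array weights (0.909). Without KO 1 and KO 2, cholesterol synthesis (0.836) and the interferon response (0.656) turned, and without KO 1, KO 2 and KO 3 the interferon response (0.419), oxidative phosphorylation (0.873) and the circadian clock (0.989). When single arrays were left out, some lists turned while their adjusted p ranged from 0.353 to 0.992 (triglyceride storage), 0.641 to 0.914 (lipolysis), 0.456 to 0.962 (mature adipocyte), 0.486 to 0.994 (macrophage), 0.384 to 0.986 (inflammatory), 0.179 to 0.962 (extracellular matrix) and 0.414 to 0.936 (flanking genes).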

Other observations

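The count of splits for genes past the adjusted threshold, the test of the time of day and the test of the feeding response were chosen after the result had been seen. The rule for the feeding response was also changed to a sign test once its value was known, because the members go both ways.

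Higher Nr1d1 and lower Nfil3, Bhlhe40 and Bhlhe41 in KO were looked at together. Nr1d1 represses the other clock arm, and Bhlhe40 and Nfil3 respond to feeding and insulin. Whether Nr1d1 links the changes of these genes was not tested. A different time of day at harvest may move some of them together. Clock genes that peak near Nr1d1 (Nr1d2, Dbp, Tef, Hlf, Per3) minus those that peak near Arntl (Arntl, Clock, Npas2, Cry1) were higher in KO by 0.761 on the log2 scale, with a pooled SD of 0.627, 3 of 5 KO arrays above the highest WT array and an exact permutation p of 0.179. Within the same-numbered pairs, KO was higher in all 3 (by 1.76, 1.05 and 0.729; exact two-sided sign-flip p = 0.25, the smallest possible with 3 pairs). Neither decides on a shift in time, and harvest times are not given in the sources used here. A weaker feeding response of the whole lipogenic programme could also lower such genes, but 10 of the 16 de novo lipogenesis genes were higher and 6 lower (median 0.0954, exact two-sided sign test p = 0.454), which leaves it open. An effect of the genotype also stays open and was not tested apart from these.

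Other divisions of the 8 arrays into 3 and 5 show how far chance can be excluded. For genes past the adjusted threshold, all 56 of the 56 splits gave as many as the real 0, which any split must, so the count says nothing about chance, and the highest other count was 12. For genes at an unadjusted p under 0.05 in limma, 3 of the 56 splits gave as many as the real 1164, so chance is not excluded, and the highest other count was 1650. For lists, 29 of the 56 splits gave as many as the real 3, and the highest other was 9, so chance is not excluded there either. The highest gene counts (12 and 1650) came from setting KO 1, KO 2 and KO 3 against the rest. A structure among the arrays apart from genotype may lie behind this. Some split must be highest, however, and no test set these 3 arrays against KO 4 and KO 5 alone. The fit without KO 1, KO 2 and KO 3 gave 1238 genes at an unadjusted p under 0.05 in limma, with 1 gene and 0 lists passing. On the first principal component (29.8% of the variance) KO 3 (-1.57) lay by WT 2 (-0.607) and far from KO 1 (32.0) and KO 2 (21.95). On the second (21.5%), all 3 WT arrays lay above 0 (6.31 to 30.8) and all 5 KO arrays below it (-17.7 to -1.68), with KO 3 at -10.6. Among the 8 splits that part all 3 same-numbered pairs, 2 gave as many genes (highest other 1650) and 5 as many lists (highest other 9).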
